A study of Mus musculus with 8 samples.

How the data were processed

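Total RNA of Lacun3 cells was extracted from 4 parental and 4 Stk11 knockout cultures, grown in the same medium without treatment, per the labels' protocols. Libraries were made from 100 ng of RNA with the Illumina Stranded mRNA Prep kit and sequenced as paired reads of 51 bp on a NextSeq 2000, per the labels' protocols. The submitters' processing notes name FastQC 0.11.8, STAR 2.7.9a, featureCounts 1.6.0, edgeR and limma and the genome build GRCm39, without saying which step each carried out. The parameters, the treatment of reads that map to several places and the strand setting are not given in the sources used here. Genes with near-identical copies, genes that overlap and antisense pairs may therefore share or lose reads, which concerns the Sprr and Serpinb families, mitochondrial genes with nuclear copies, and Stk11 with its neighbour Cbarp.

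The authors deposited raw counts per gene for 56884 annotated genes in 8 libraries, of which 27134 had at least 1 count. A second deposited table held 15726 genes as log2 CPM in voom's form. Recomputed from the raw counts, each of its libraries had a single effective library size across all its genes, with a relative spread of at most 6.9e-14. All 13707 genes tested here were in that table. Gene identifiers, symbols and positions were taken from the count table. Groups and replicate numbers came from the labels. Every sample had a group, and no sample was left out.

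The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, glmQLFit with robust estimation and glmQLFTest) on the raw counts with genotype as the only term, TMM scaling and the default filterByExpr filter. P-values were adjusted by the Benjamini-Hochberg method over the 13707 tested genes, and a gene was called changed at an adjusted p under 0.05. "Rose" and "fell" are used for genes that passed. Log2 fold changes are fitted values, knockout over parental, and their standard error is the absolute fold change over the square root of the F statistic. CPM values are raw counts over TMM-scaled library sizes, given as mean ± SD of 4 libraries. Where a group had 0 counts in all its libraries, a lower bound of the fold was computed against 3 counts over the group, and where it had 1 to 3 counts the ratio was given with an exact (Clopper-Pearson) 95% interval. Such bounds and intervals cover counting error only. Single values per library were compared by exact permutation tests over all 70 assignments (scipy 1.17.1), two-sided.

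Gene lists were written from general knowledge before the data were examined, 37 in all. The 31 with at least 5 tested members were tested with limma's camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 31 lists. A list was described on its own if camera passed, if at least 1 in 3 of its tested members changed 2-fold, or if it was among 9 lists central to the question. The named genes followed a rule also fixed before the data were examined: Stk11; the 10 largest rises and the 10 largest falls among genes passing the test with at least 5 CPM in the higher group and no overlap between groups, passing over predicted genes; and for each described list the up to 2 risers and 2 fallers with the smallest adjusted p. Not every gene that the rule takes is named in the text. Genes named outside this rule are said to be so. Marker lists of other cell types were given as levels.

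Alternatives fixed before the data were examined were other scalings (DESeq2's size factors, upper quartile, library size alone), no filter or a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, limma on the deposited voom values, edgeR's legacy quasi-likelihood, glmTreat against a log2 fold change of 1, the replicate number as a block, camera with an estimated correlation, fry, and leaving out each library in turn. The steps were tested on simulated data drawn for the 13707 genes from the means and library sizes of this comparison. Of 200 genes changed by known folds, 83.6% were recovered at 1.5-fold, 89.6% at 2-fold and 98.5% at 4-fold. In this simulation 4% of calls were false, and the 1 moved list was the only one of 31 called. Genes were drawn independently of each other and few were changed, whereas 9322 genes passed in the data and list correlations were estimated at up to 0.546. The simulated error rates, above all for lists, therefore need not hold for the data. Library sizes of 18837263 to 25715008 counts set the precision: 1 count corresponded to 0.0388 to 0.0515 CPM, and 3 counts over a group to 0.0358 CPM in the parental and 0.0338 CPM in the knockout group. The computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.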

Results

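The series measured messenger RNA by bulk RNA sequencing in Lacun3, a mouse lung adenocarcinoma cell line, as the parental line and as a line in which Stk11 had been targeted with CRISPR. Stk11 encodes LKB1, a tumour suppressor kinase that activates AMPK and its relatives. Each genotype had 4 libraries, described by the submitters as independent biological replicates of untreated cultures harvested in logarithmic growth. The comparison asks which transcripts change inside the tumour cells when Stk11 is disrupted, away from stroma and immune cells. Libraries held 18837263 to 21101904 counts in the parental group and 21441601 to 25715008 in the knockout group, so that 1 count was worth 0.0388 to 0.0515 CPM, the unit of counts scaled to library size. Library size was higher in the knockout group (exact permutation test, two-sided p = 0.0286, n = 4 per group, the smallest p that this design allows). Mitochondrial genes took 2.09% ± 0.155 of counts (SD, n = 4) in parental and 1.57% ± 0.259 in knockout libraries (exact permutation test, two-sided p = 0.0571), and the 10 most abundant genes of a library took 5.61% ± 0.0443 and 6.52% ± 0.318 (exact permutation test, two-sided p = 0.0286). Pseudogenes took 0.528% ± 0.015 and 0.68% ± 0.0356 of counts (SD, n = 4; exact permutation test, two-sided p = 0.0286). Ribosomal RNA genes and the number of genes with a count gave an exact permutation p of 0.971 and 0.114 (two-sided). Across genes, log2 CPM correlated at 0.991 to 0.994 between libraries of the same genotype and at 0.937 to 0.941 between genotypes; genes are not independent replicates. No pair of libraries in a group agreed within sampling noise: the chi-square of their counts per degree of freedom ran from 3.31 to 21.1. Every pair with knockout replicate 3 lay between 14.5 and 21.1, the highest with knockout replicate 1, and no other pair lay above 9.85.

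Stk11 mRNA was lower in every knockout library, and a large part of it remained. The gene (ENSMUSG00000003068.18) lies on the plus strand of chromosome 10 from position 79951637 to 79966516 in GRCm39. Its level was 66.3 ± 1.79 CPM (SD, n = 4) in parental libraries, with single values of 64.9, 67.1, 68.4 and 64.7 CPM, and 34.7 ± 0.853 CPM (SD, n = 4) in knockout libraries, with single values of 35.4, 35.1, 33.5 and 35.0 CPM. The log2 fold change was -0.93 ± 0.06 (SE; edgeR quasi-likelihood test, adjusted p = 2.03e-12), which left 52.4% of the parental level with a 95% interval of 48.4% to 56.6%. An exact permutation test of the 8 values gave a two-sided p of 0.0286 (n = 4 per group), the smallest possible. The counts cover the whole gene, so they do not show whether the remaining transcripts carry an edit or encode a protein. The last 232 bp of Stk11 overlap Cbarp on the minus strand, and the strand setting used for counting is not given in the sources used here; Cbarp, chosen after its values were seen because of this overlap, had a log2 fold change of 0.82 ± 0.10 (SE).

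**Figure D1:**
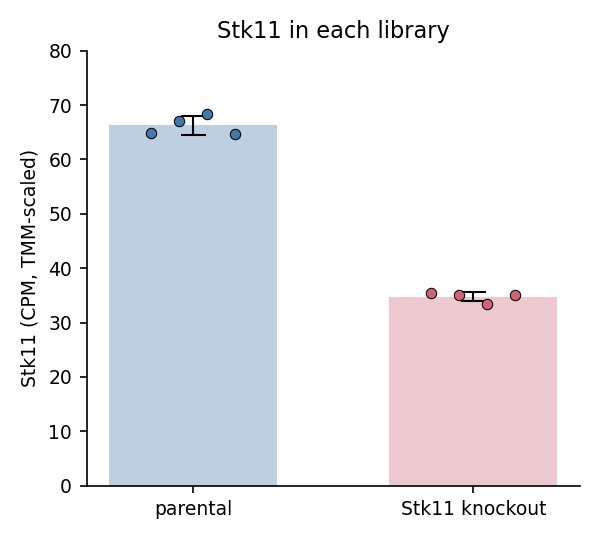
Stk11 level in CPM (vertical axis, TMM-scaled, starting at 0) in the parental and Stk11 knockout groups. Points are single libraries, bars are group means and error bars are SD (n = 4). The knockout libraries lie between 33.5 and 35.4 CPM and the parental libraries between 64.7 and 68.4 CPM.

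The knockout cells differed from the parental cells in most of the genes that had enough counts to be tested. Among the largest rises were genes almost silent in parental cells. Cd93, a transmembrane lectin-like receptor best known from endothelium, and Il6, an inflammatory cytokine, had 0 counts in all parental libraries together and were at least 250-fold and at least 176-fold higher in the knockout, against a floor of 3 counts over the group. Chil1, a secreted chitinase-like protein, rose from 0.454 ± 0.159 to 110 ± 11.7 CPM (SD, n = 4) and Pde4b, a cAMP-degrading phosphodiesterase, from 0.575 ± 0.162 to 134 ± 11.8 CPM. Wnt7a, a secreted Wnt ligand, fell from 24.6 ± 1.19 to 0.228 ± 0.0729 CPM, and Gas6, a ligand of the Axl receptor family, from 11.5 ± 1.68 to 0.259 ± 0.0976 CPM.

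Of 13707 tested genes, 9322 (68%) passed the edgeR quasi-likelihood test at an adjusted p under 0.05, with 4721 higher and 4601 lower in the knockout. The median absolute log2 fold change of these genes was 0.55, and 2252 of them changed at least 2-fold, 962 upward and 1290 downward. In 60.6% of tested genes the 4 knockout values did not overlap the 4 parental values, where chance gives 2.9%. The other genes among the 10 largest rises were Angptl8, a regulator of lipoprotein lipase (log2 fold change 7.54 ± 0.17, SE), Gng2, a G protein subunit (6.92 ± 0.19), Bend4 (6.82 ± 0.32), the Ly6 family member Ly6m, and the amino acid transporter genes Slc6a14 and Slc7a8. These last genes had 2 or 3 counts in the whole parental group: the ratio of knockout to parental counts per effective library size was 428 for Ly6m (95% counting interval 146 to 2077), 249 for Slc6a14 (68.7 to 2064) and 220 for Slc7a8 (74.9 to 1068). Without parental replicate 2 the fitted log2 fold change of Slc7a8 moved from 7.56 to 8.49. Among the 10 largest falls, Klhl13, an adaptor of a ubiquitin ligase, had 438 parental counts and 2 knockout counts, a parental-to-knockout ratio of 232 (95% counting interval 63.8 to 1921). The remainder were Rasal1, a Ras GTPase-activating protein (log2 fold change -6.25 ± 0.32, SE), Elapor1 (-6.06 ± 0.25), Itih5 (-5.69 ± 0.27), Bmp2, a bone morphogenetic protein (-5.27 ± 0.25), Slc40a1, the iron exporter ferroportin (-5.23 ± 0.20), Slc1a3, a glutamate transporter (-5.16 ± 0.23), and Stmn2, a microtubule regulator (-5.09 ± 0.17). The largest edgeR adjusted p among these 20 genes was 1.6e-12, for Il6. The number of genes changed at least 2-fold depended on the criteria: 1351 genes passed a test against a log2 fold change of 1 (edgeR glmTreat), and 3461 passed when no filter on low counts was used. The labels name 1 edited and 1 parental line, so the counts describe a difference between these lines.

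**Figure D2:**
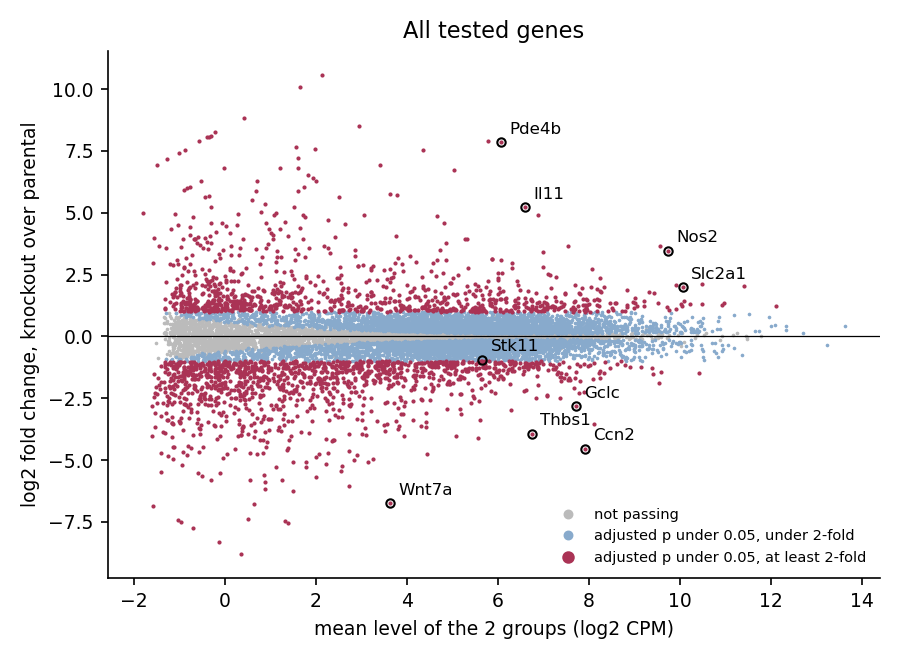
Log2 fold change of knockout over parental (vertical axis) against the mean of both group means in log2 CPM (horizontal axis) for the 13707 tested genes. Grey points did not pass, blue points passed under 2-fold and red points are the 2252 genes that passed with at least a 2-fold change; values of genes with 0 counts in a group are fitted values and no measured fold. Changed genes lie on both sides of 0 at every expression level.

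Gene lists were set against all other tested genes with camera. Of all tested genes 68% passed, 4721 higher and 4601 lower in the knockout. Members that moved both ways are therefore no trait particular to a list. Of 31 lists with at least 5 tested members, 15 passed at an adjusted p under 0.05, 10 upward and 5 downward in the knockout. These camera values assume a correlation of 0.01 between genes of a list. With an estimated correlation only the YAP-TEAD list passed, where the estimate was -0.031, below the preset. It was also below the preset for the NF-kB list (-0.028), which lost its call, so a higher correlation does not account for every lost call. Other divisions of the 8 libraries into 4 and 4 gave up to 13 lists by the same preset. In these divisions no gene passed edgeR's test and 22 to 1315 genes had an unadjusted p under 0.05. Adjusted over the list alone, the number of changed members differed from the number given below for 4 lists, the human LKB1-loss signature (11 against 10), MHC class I (20 against 19), glycolysis and hypoxia (28 against 27) and ER chaperones (13 against 12). Several lists share members, and such a gene was counted under each of them. List medians were the same with genes of 0 counts set at their bound. Scaling by library size alone shifted the medians of the 31 lists by -0.09 to -0.08. Among the genes named by the rule only Sfn had groups that overlapped.

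Genes of the pathway around LKB1 moved both ways, and known targets of the CREB coactivators CRTC, which LKB1 signalling restrains through the SIK kinases, were mostly higher. Of 18 tested CREB-CRTC targets, 13 rose, 4 fell and 1 did not pass, with a median log2 fold change of 1.10 (camera adjusted p = 4.74e-05; adjusted p = 0.0841 with an estimated correlation). Beside Pde4b, the phosphodiesterase gene Pde4d rose from 26.5 ± 1.33 to 75.0 ± 1.42 CPM (SD, n = 4). In the opposite direction, the insulin receptor substrate gene Irs2 fell 2.63-fold and the immediate-early nuclear receptor gene Nr4a1 fell 1.84-fold (edgeR adjusted p = 2.27e-14 and 2.29e-09). Of 21 tested genes for the LKB1 complex and AMPK-family kinases, 9 rose and 6 fell; scaled by library size alone 6 rose and 9 fell. The AMPK subunit genes Prkab2 (log2 fold change 1.07 ± 0.09, SE) and Prkag1 (0.66 ± 0.07) rose, while Mark1, which encodes an AMPK-related kinase, fell from 4.55 ± 0.758 to 0.383 ± 0.154 CPM. The list did not pass (camera adjusted p = 0.714), and its median of 0.10 and its mean of -0.17 differed in sign. A signature of LKB1 loss described in human lung tumours had 6 of 12 tested members higher and 4 lower. Its median was 0.12, its mean -0.32 and its camera direction up (camera adjusted p = 0.316). Within the signature, Tacc2, a centrosome-associated coiled-coil gene, rose 2.05-fold. Tesc, a calcium-binding protein gene, had 215 parental and 0 knockout counts and was at least 75.9-fold lower. The mean of -0.32 includes the fitted value of Tesc, -8.79. As mean log2 differences from the parental mean, knockout replicates 1 to 4 gave 0.095, 0.010, -0.268 and 0.077.

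Secreted immune mediators changed strongly and in both directions. Of 34 tested cytokine and chemokine genes, 20 rose, 11 fell and 3 did not pass, with 16 rises and 9 falls of at least 2-fold (camera direction up, adjusted p = 0.000285; adjusted p = 0.188 with an estimated correlation). Il11, an interleukin-6 family cytokine, rose from 4.99 ± 0.651 to 188 ± 19.7 CPM (SD, n = 4) and Ccl2, a monocyte chemoattractant, from 30.2 ± 3.35 to 142 ± 2.86 CPM. Csf1, the macrophage growth factor, fell from 60.5 ± 1.71 to 12.1 ± 0.862 CPM and Cx3cl1, a membrane-bound chemokine, from 228 ± 5.56 to 43.3 ± 6.02 CPM. Among 20 NF-kB targets, 13 rose and 6 fell (camera adjusted p = 0.0177; adjusted p = 0.135 with an estimated correlation). Their median log2 fold change was 0.31 and their mean 0.81, which includes the fitted 10.08 of Il6 with 0 parental counts. Cxcl1, Cxcl2, Ccl20 and Il6 also belong to the cytokine list, so this list is not separate from it. The neutrophil chemokine genes Cxcl1 and Cxcl2 rose 2.56-fold and 3.63-fold, whereas Ccl20 and the adhesion molecule gene Icam1 fell 4.63-fold and 3.06-fold; the largest edgeR adjusted p of these 4 genes was 1.31e-13, for Icam1.

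Interferon-response and MHC class I genes moved both ways, as did the tested genes as a whole, of which 68% passed. Of 27 tested interferon and cGAS-STING genes, 8 rose, 10 fell and 9 did not pass (camera direction down, adjusted p = 0.68; up without knockout replicate 3, adjusted p = 0.892, in a range of 0.547 to 0.892 over camera's alternatives). Oas3 and Gbp2, both interferon-induced, rose 1.76-fold and 3.46-fold, and Irgm1 and Bst2, interferon-induced as well, fell 3.14-fold and 2.63-fold (largest edgeR adjusted p 2.43e-08, for Gbp2). Of 22 MHC class I genes, 7 rose and 12 fell (camera adjusted p = 0.389). B2m, the light chain of MHC class I, fell from 208 ± 6.65 to 131 ± 13.2 CPM (SD, n = 4) and the chaperone gene Tapbp fell 1.72-fold, while Tapbpl, its relative, rose 2.56-fold and the transactivator gene Nlrc5 rose by a log2 fold change of 2.22 ± 0.29 (SE). All 3 tested MHC class II pathway genes fell at low levels: Cd74 by 2.34 ± 0.19 and H2-DMa by 2.06 ± 0.17 on the log2 scale (SE), the other being H2-Ab1, chosen after its values were seen because the count is small. Of 15 checkpoint and costimulatory ligand genes, 4 rose and 6 fell (camera adjusted p = 0.68). Cd274, which encodes PD-L1, fell from 11.8 ± 2.03 to 1.78 ± 0.320 CPM and Lgals9 from 70.2 ± 2.40 to 35.1 ± 2.05 CPM, while Ceacam1 rose 5.49-fold and Nectin2 1.32-fold (largest edgeR adjusted p 4.11e-06, for Nectin2). In knockout replicate 3 the mean of the interferon list lay 0.449 below the parental mean on the log2 scale, and in the other 3 knockout libraries between 0.096 below and 0.004 above it.

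Most glycolysis and hypoxia genes rose. Of 29 tested members, 25 rose and 2 fell, with a median log2 fold change of 0.74 (camera adjusted p = 1.87e-08; adjusted p = 0.188 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, rose from 428 ± 27.4 to 1716 ± 167 CPM (SD, n = 4) and Bnip3, a hypoxia-induced mitophagy receptor, from 139 ± 1.67 to 480 ± 26.6 CPM. Pfkm and Pfkfb3, which act at the phosphofructokinase step, fell, with log2 fold changes of -1.03 ± 0.06 and -0.58 ± 0.07 (SE). Nuclear-encoded oxidative phosphorylation genes shifted slightly upward, with 25 of 39 higher, 3 lower and none changed 2-fold (median 0.20; camera adjusted p = 0.0177; adjusted p = 0.722 with an estimated correlation). By library size alone 19 rose and 6 fell, with a median of 0.12. Examples were the ATP synthase subunit gene Atp5b (log2 fold change 0.77 ± 0.06, SE) and the succinate dehydrogenase gene Sdhb (0.66 ± 0.06), against falls of Cox7a2 (-0.34 ± 0.07) and Uqcrfs1 (-0.18 ± 0.06; edgeR adjusted p = 0.00729). Of 8 tested mitochondrially encoded mRNAs, 6 fell and 2 did not pass; the list had a camera adjusted p of 0.247, and of 0.0415 without knockout replicate 4, in a range of 0.0415 to 0.722 over camera's alternatives. Of the 13 mitochondrial genes of the list, 6 neighbouring ones from mt-Co2 to mt-Nd4l, named here after their values were seen, had at most 20 counts in any library, against at least 605 for each of the others, so the list and the mitochondrial share of counts cover part of these mRNAs.

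Sterol and fatty acid synthesis genes were mostly higher and lysosomal genes mostly lower. In the cholesterol and fatty acid list 21 of 30 members rose and 6 fell (median 0.74; camera adjusted p = 0.00129; adjusted p = 0.608 with an estimated correlation). The sterol synthesis genes Lss and Sqle rose 2.79-fold and 2.10-fold (largest edgeR adjusted p 2.56e-12, for Sqle). Of 32 autophagy and lysosome genes, 19 fell, 5 rose and 8 did not pass (median -0.27; camera adjusted p = 0.0364; adjusted p = 0.608 with an estimated correlation); the camera value was 0.0564 without knockout replicate 2 and 0.0539 with a filter of at least 1 CPM in 4 libraries, within a range of 0.0125 to 0.608 over camera's alternatives. The lysosomal hydrolase genes Neu1 and Gaa fell 2.03-fold and 1.72-fold, while Npc1 and Atg9a rose 1.43-fold and 1.51-fold. Fatty acid oxidation genes went both ways, with 8 of 20 higher and 7 lower (6 and 9 scaled by library size alone; camera adjusted p = 0.631).

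Most targets of the amino acid stress factor ATF4 rose. Of 22 tested targets of ATF4 and the integrated stress response, 17 rose, 2 fell and 3 did not pass, with a median log2 fold change of 1.21 (camera adjusted p = 3.86e-11; adjusted p = 0.135 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, rose from 31.8 ± 4.00 to 223 ± 15.3 CPM (SD, n = 4) and Asns, asparagine synthetase, from 195 ± 5.15 to 723 ± 29.3 CPM; Stc2 fell 3.00-fold and Atf3 1.38-fold (edgeR adjusted p = 0.000527 for Atf3). In the one-carbon, serine and methylation list 10 of 17 members rose and 4 fell (camera adjusted p = 0.00307; adjusted p = 0.137 with an estimated correlation). The serine synthesis gene Psph rose 5.19-fold, while Shmt1, a folate enzyme, and Mat2a, which makes S-adenosylmethionine, fell 2.85-fold and 2.41-fold. Of 10 urea cycle and arginine genes, 6 rose and 3 fell (camera adjusted p = 0.0694). That camera value fell under the threshold without parental replicate 4 (0.0472) or knockout replicate 1 (0.0127), with the replicate block (0.0256), by library size alone (0.0471) and with a filter of at least 1 CPM (0.0466), in a range of 0.0127 to 0.22 over camera's alternatives. Nos2, the inducible nitric oxide synthase, rose from 142 ± 14.3 to 1569 ± 264 CPM and Odc1, of polyamine synthesis, from 609 ± 20.1 to 1492 ± 125 CPM; Glul and Cad fell 1.66-fold and 1.26-fold. The ER chaperone list, which belongs to another stress pathway, did not pass (8 of 17 higher and 4 lower, or 5 and 7 scaled by library size alone; camera adjusted p = 0.714).

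Genes of the NRF2 list, most of them antioxidant targets, mostly fell. The list also holds Nfe2l2, which encodes NRF2, and Keap1, named here only to define it. Of 21 tested members, 16 fell, 3 rose and 2 did not pass, with 8 falls of at least 2-fold and a median log2 fold change of -0.70 (camera adjusted p = 5.47e-10; adjusted p = 0.135 with an estimated correlation). Gclc, the catalytic subunit of glutathione synthesis, fell from 370 ± 23.7 to 52.0 ± 1.97 CPM (SD, n = 4) and the glutathione transferase gene Gstm1 from 196 ± 7.77 to 34.6 ± 2.60 CPM. Hmox1, heme oxygenase, and Osgin1 rose, with log2 fold changes of 0.58 ± 0.06 and 0.67 ± 0.06 (SE; edgeR adjusted p = 3.77e-08 and 3.11e-09).

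All 13 tested YAP-TEAD targets fell, under each of the 4 scalings run, with a median log2 fold change of -0.62 (camera adjusted p = 5.47e-10; adjusted p = 0.0136 with an estimated correlation). Ccn2, a matricellular protein, fell from a mean of 460 to 19.9 ± 2.41 CPM (SD, n = 4; log2 fold change -4.54 ± 0.07, SE) and Ankrd1, a stretch-responsive transcriptional cofactor, from 71.7 ± 1.89 to 25.1 ± 1.07 CPM. Of 7 WNT targets, 6 fell and 1 rose (median -1.49; camera adjusted p = 4.74e-05; adjusted p = 0.135 with an estimated correlation). Myc fell from 1007 ± 17.4 to 355 ± 12.3 CPM and Ccnd1, which encodes cyclin D1, from 2028 ± 67.2 to 721 ± 29.3 CPM, while Rnf43, a ubiquitin ligase that removes Wnt receptors, rose 2.85-fold (edgeR adjusted p = 1.75e-12). MAPK output genes went both ways, 11 of 22 up and 6 down (camera adjusted p = 0.184). Ereg, an EGF receptor ligand, and the ephrin receptor gene Epha2 rose 4.04-fold and 2.28-fold, and Epha4 fell 2.17-fold. Of 13 TGF-beta targets, 5 rose and 3 fell, or 5 and 5 scaled by library size alone (median 0.00, mean -0.26; camera direction down, adjusted p = 0.391). Bhlhe40 and Skil, both transcriptional regulators, rose 2.92-fold and 1.49-fold, and Id2, an inhibitor of helix-loop-helix factors, fell from 28.9 ± 1.36 to 1.79 ± 0.651 CPM.

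Proliferation genes were mostly higher, genes of the p53 list mostly lower. Of 30 cell cycle genes, 21 rose, 4 fell and 5 did not pass (median 0.51; camera adjusted p = 0.000586; adjusted p = 0.439 with an estimated correlation). The proliferation marker Mki67 rose from 172 ± 13.2 to 346 ± 3.32 CPM (SD, n = 4) and Tyms, thymidylate synthase, 2.95-fold; the replication helicase gene Mcm6 fell 1.37-fold beside the fall of Ccnd1. The p53 list was written with Trp53 itself and Cdkn2a beside p53 targets. Of its 21 tested members, 14 fell, 2 rose and 5 did not pass (median -0.37; camera adjusted p = 0.0278; adjusted p = 0.647 with an estimated correlation). Plk2 and Ccng1 fell 2.69-fold and 1.91-fold, and Cdkn1a, the cell cycle inhibitor p21, and the death receptor gene Fas rose 1.55-fold and 1.32-fold (edgeR adjusted p = 0.000784 for Fas).

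**Figure D3:**
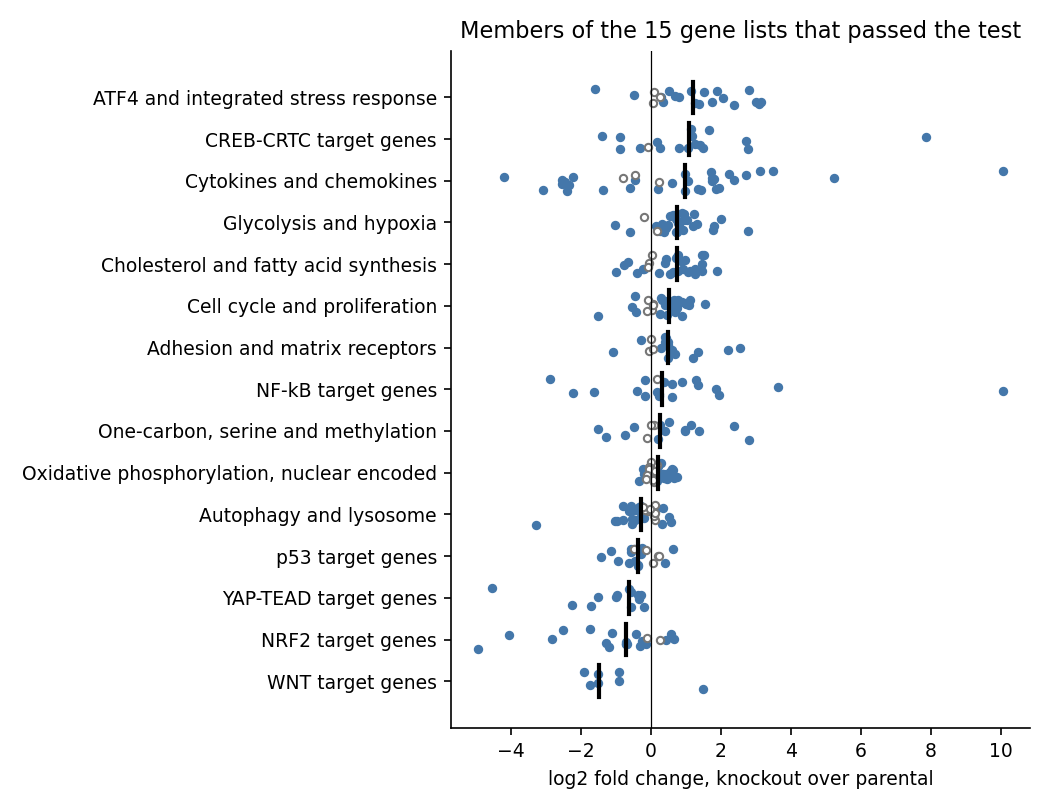
Log2 fold changes of knockout over parental (horizontal axis) for the tested members of the 15 lists that passed camera. Filled points passed edgeR's test, open points did not and black bars are list medians, from 1.21 for the ATF4 list to -1.49 for the WNT list; the point of Il6, with 0 parental counts, is a fitted value.

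Neither the epithelial nor the mesenchymal list passed camera, though the epithelial mean was lower in every knockout library. Of 20 tested epithelial genes, 10 fell and 5 rose (median -0.24; camera adjusted p = 0.091). As log2 differences from the parental mean, the list means were -0.436 to -0.292 in knockout and -0.064 to 0.042 in parental libraries. By fry, which does not compare a list with other genes, the direction was down (adjusted p = 0.000326). The keratin gene Krt7 fell from 1181 ± 25.4 to 317 ± 35.7 CPM (SD, n = 4) and the tight junction gene Cldn6 2.18-fold, while Elf3, an epithelial transcription factor, and the desmosomal gene Dsp rose 3.37-fold and 1.29-fold. Of 19 mesenchymal genes, 10 rose and 6 fell (median 0.24, mean -0.05; camera direction down, adjusted p = 0.919). Its camera direction was up without knockout replicate 2 (adjusted p = 0.843) or 4 (0.944), in a range of 0.777 to 0.96 over camera's alternatives. The collagen gene Col5a1 rose 3.91-fold and Snai2, a repressor of epithelial genes, from 0.465 ± 0.124 to 5.37 ± 0.904 CPM; Thbs1, thrombospondin, fell from 203 ± 15.4 to 13.3 ± 1.32 CPM and Sparc, a matrix glycoprotein, 4.60-fold. The largest edgeR adjusted p of these 8 genes was 1.65e-05, for Dsp. Among 19 adhesion and matrix receptor genes, 14 rose and 2 fell (median 0.49; camera adjusted p = 0.000367; adjusted p = 0.532 with an estimated correlation). The integrin gene Itgb3 rose 5.90-fold and the laminin gene Lamb3 2.53-fold, and Itgb5 and Lama5 fell 2.09-fold and 1.22-fold.

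Lineage genes of lung, squamous and gastric epithelium were few and went both ways. Of 8 tested alveolar and airway genes, 1 rose, 4 fell and 3 did not pass (camera adjusted p = 0.247). The water channel gene Aqp5 fell from 91.2 ± 2.63 to 33.3 ± 2.09 CPM (SD, n = 4) and Muc1 fell 2.92-fold. Pdpn rose at a low level, from 0.0977 ± 0.0896 to 0.865 ± 0.383 CPM, with 8 parental and 75 knockout counts. Among 7 squamous and basal genes 3 rose and 4 fell (median -0.57, mean 0.19; camera direction up, adjusted p = 0.68). The cornified envelope gene Sprr1b and the plakophilin gene Pkp1 rose 5.66-fold and 1.47-fold, and Perp and Sfn fell 1.48-fold and 2.10-fold (edgeR adjusted p = 0.0149 for Sfn, whose groups overlapped). Of 7 gastric and mucinous genes, 2 rose and 5 fell (median -0.57, mean -0.02; camera direction down, adjusted p = 0.162). Hnf4a, a transcription factor of gut epithelium, fell from 58.1 ± 1.71 to 24.3 ± 1.22 CPM and the protease gene Ctse 3.43-fold, while Foxa3 and the trefoil factor gene Tff1 rose from under 1 CPM to 4.21 ± 0.739 and 4.27 ± 1.34 CPM.

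Markers of other cell types were low, with few exceptions. Under 1 CPM in every library were 20 of 21 leukocyte, 11 of 12 fibroblast, 8 of 12 endothelial, 7 of 7 erythroid and 9 of 10 neuroendocrine markers. The exceptions fell in the knockout for Cd68, a lysosomal glycoprotein of macrophages, from 48.9 ± 2.82 to 19.2 ± 5.11 CPM (SD, n = 4), for the VEGF receptor gene Flt1 from 113 ± 4.47 to 50.3 ± 5.24 CPM, for Vwf from 1.56 ± 0.496 to 0.125 ± 0.0624 CPM and for Col6a3 from 1.03 ± 0.143 to 0.236 ± 0.113 CPM. Cdh5, an endothelial cadherin, rose from 1.36 ± 0.327 to 4.17 ± 0.624 CPM. Egfl7 and Ncam1, chosen after their values were seen to complete the markers above 1 CPM, fell by 0.23 and rose by 0.66 on the log2 scale; the groups overlapped for Egfl7.

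**Figure D4:**
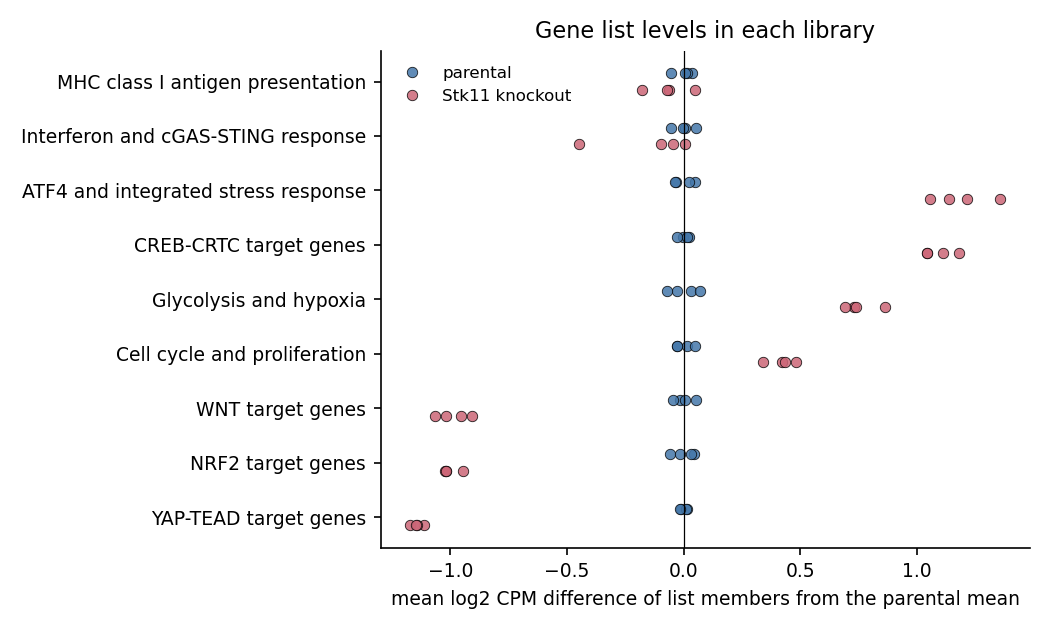
Mean log2 CPM difference of a list's members from the parental mean (horizontal axis) in each of the 8 libraries for 9 lists. Each point is 1 library. The knockout libraries lie between -1.17 and -1.11 for the YAP-TEAD list and between 1.06 and 1.36 for the ATF4 list, clear of the parental libraries, and overlap them for the interferon and MHC class I lists.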

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

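All tests of explanations in this part were chosen after the results they bear on were seen. Among 327 groups of 4 values (named genes, list means and library measures), 18, or 5.5%, held a library set apart from the rest. Its gap to the nearest other, over the group's range, exceeded Dixon's 95% critical value. For independent values chance flags about 1 in 20 groups. These groups share the same 8 libraries, and many genes were taken by their test, so that rate is no firm yardstick. Knockout replicate 3 and parental replicate 3 held 5 each. In knockout replicate 3, Bmp2 was at 0.117 CPM (others 0.185 to 0.198), Ccng1 at 295 (356 to 362) and Stc2 at 40.5 (30.3 to 30.8). Its list means, as log2 differences from the parental mean, were 0.416 for cytokines (0.549 to 0.556) and -0.946 for the NRF2 list (all others -1.02). In knockout replicate 1, Pdpn was at 1.44 CPM (0.622 to 0.707) and the NF-kB list at 0.557 (0.619 to 0.621). In parental replicate 3, Ly6m was at 0 CPM (0.0464 to 0.0515), Gbp2 at 0.871 (1.19 to 1.24), Hmox1 at 26.1 (28.2 to 28.6), Lama5 at 2046 (1736 to 1780), and 20870 genes had a count (20280 to 20370, all rounded to 4 digits). In parental replicate 4, Gas6 was at 8.96 CPM (12.1 to 12.6), Muc1 at 4.74 (3.01 to 3.30) and Atf3 at 9.89 (10.4 to 10.5). In parental replicate 1, Psph was at 17.1 CPM (21.7 to 22.5) and the checkpoint ligand list at 0.064 (-0.028 to -0.015), and in parental replicate 2 ribosomal RNA genes took 0.45% of counts (0.13% to 0.18%).

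A large part of the Stk11 mRNA, 52.4%, remained in the knockout libraries. If unedited parental cells supplied all of it and kept their parental expression, no gene could lie below the 48.4% that is the lower limit of that share. Yet of 10195 genes with at least 5 CPM in parental cells 441 passed the edgeR test below it, and 44 had an upper 95% limit under 10%. A first criterion, more than 5% of all such genes, was not met at 4.4%. That criterion was dropped after it had been computed, because genes that did not fall say nothing about that level. Whether unedited cells would keep their parental expression beside edited ones was not tested. Loss of 1 copy of the surrounding chromosome segment would lower its neighbours alike, but the 61 genes with at least 5 CPM within 1 Mb had a median log2 fold change of 0.12 (bootstrap 95% interval -0.08 to 0.27) against -0.93 for Stk11, although 5 of them fell as far. A smaller deletion, or decay of transcripts edited by CRISPR, stays open and untested, since the table gives 1 count per gene.

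The breadth of the change, 9322 genes, was not reached in any other of the 35 divisions of the 8 libraries into 4 and 4. The highest other count was 0 genes by edgeR, with up to 1315 at an unadjusted p under 0.05, and 0 by limma-voom. The same holds for the 2252 genes changed at least 2-fold (1 of 35, highest other 0). Every other division mixed the genotypes, so a genotype difference adds to its spread, and these counts of 0 add nothing beyond the rank. By that rank, 1 of 35 and the lowest share the design allows, a chance division is argued against. The choice among the scalings run does not account for the breadth: by library size alone 91.4% of the calls were kept. That choice moved the median log2 fold change of all genes only from 0.01 to -0.07. The median absolute log2 fold change of the called genes was 0.55. All scalings run are relative, so a change in total mRNA per cell would not show and stays untested. Gains or losses of whole chromosomes that act only on the genes they carry do not account for it either. At least 63.5% of tested genes changed on each of the 20 chromosomes with at least 100 tested genes. Chromosome medians ran from -0.09 to 0.14. Effects of a gained or lost chromosome on genes elsewhere would not show in these values and stay open and untested. Divergence between the edited and the parental line that is unrelated to Stk11 cannot be told apart from an effect of Stk11, because the labels give 1 knockout and 1 parental line and do not say whether the former is a clone or a pool; libraries correlated at no more than 0.941 between the lines. An effect of Stk11 loss, the difference the design names, remains among the open explanations.

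The YAP-TEAD and NRF2 lists were lower while the hypoxia and ATF4 lists were higher in all 4 knockout libraries. The choice between TMM and library size alone is argued against as the whole cause. By library size alone 97.4% of the 78 called members of these 4 lists kept their call and direction. These scalings differ little, by -0.09 to -0.08 in the list medians. Both are relative, so a change in total mRNA per cell would not show. Growth arrest in denser knockout cultures is argued against as well: the cell cycle list had a median log2 fold change of 0.51, and its mean was higher in each knockout library than in any parental one (exact permutation test, two-sided p = 0.0286, n = 4 per group), although Ccnd1 fell 2.81-fold, Cdkn1a rose 1.55-fold and the list had a camera adjusted p of 0.439 with an estimated correlation. Depleted medium in the knockout cultures cannot be told apart from an effect of the genotype, because cultures of different genotype were always separate and no record of medium or density was used here, beyond the labels' harvest in logarithmic growth; the lowest knockout library lay 1.057 above the parental mean in the ATF4 list. The cell cycle list speaks to arrest only, so a difference in density without arrest also stays open and untested. Loss of Stk11 itself remains open and was not tested apart from these.

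For the count of gene lists, the real division gave 15 and the highest of the other 34 gave 13 (1 of 35 gave as many). That rank is the lowest share the design allows. The margin is narrow beside the 14 to 16 lists found when 1 library was left out. Of the other divisions, which all mix the genotypes, 33 gave at least 1 list by the same preset. The rank therefore does not exclude chance for the count, nor does it speak for any single list. The 18 divisions with 2 libraries of each genotype on both sides still gave up to 9 lists; the cause was not tested.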

How the results depend on the processing

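Stk11 passed with a negative log2 fold change under all 18 alternatives run, from -1.02 by library size alone to -0.91 without knockout replicate 3. The count of changed genes ran from 8723 with a filter of at least 1 CPM to 10335 with no filter, and from 8921 to 9656 when 1 library was left out. No gene passed in the opposite direction under any of these settings. The share of calls that were higher in the knockout was 50.6%, and 42.6% by library size alone, which moved the median log2 fold change of all genes from 0.01 to -0.07. Genes changed at least 2-fold numbered 3461 with no filter on low counts, where 27134 genes were tested, and 1351 by edgeR's glmTreat, which asks for a change beyond 2-fold. Leaving out 1 library gave 2344 to 2445 such genes. The count of lists was 1 with an estimated correlation and 27 with fry, which does not compare a list with other genes, and 14 to 16 when 1 library was left out. The lists' calls stayed on their side of the threshold in 395 of 434 alternatives, lost it in 16, gained it in 18, and changed direction in 5, all of lists that did not pass: mesenchymal genes pointed upward with a filter of at least 1 CPM (camera adjusted p = 0.898), with the replicate block (0.909) and without knockout replicate 2 (0.843) or 4 (0.944), and interferon genes without knockout replicate 3 (0.892). With 1 library left out the camera adjusted p ran from 0.777 to 0.958 for mesenchymal and from 0.547 to 0.892 for interferon genes; the cause was not tested. All 127 other genes taken by the rule for named genes kept direction and call in 1524 alternatives. Same-numbered libraries of both groups did not deviate together (correlations of 0.04, 0.01, -0.10 and 0.00). These values gave no sign of a pairing by number, though a weak one could go unseen. With the replicate block 9182 genes, 2248 genes changed at least 2-fold and 16 lists passed. Depth limits the fold of genes with 0 to 3 counts in a group.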

Other observations

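Gene families, formed from the symbol's letters before its first digit, were tested for an excess of 2-fold changes among 9638 protein-coding genes. Of these genes 5.7% rose and 9.2% fell at least 2-fold. The test takes the genes of a family as independent of each other. Members that are regulated together would make its p-values too small. All tests and gene names in this part were chosen after the values were seen. Of 202 families with at least 8 tested genes, an excess of rises (Fisher's exact test, one-sided, adjusted over 404 tests) was found for Sprr, small proline-rich proteins of the cornified envelope (7 of 9, adjusted p = 2.44e-05), and for interleukins and their receptors (9 of 31, adjusted p = 0.00487). In the interleukin family 6 members fell at least 2-fold, and with smaller changes included 12 rose and 14 fell. An excess of falls was found for collagens (9 of 19, adjusted p = 0.00363), cytochromes P450 (9 of 21, adjusted p = 0.00487) and Serpinb, intracellular serine protease inhibitors (6 of 11, adjusted p = 0.0149), beside rises of at least 2-fold in 5 collagen, 5 cytochrome P450 and 2 Serpinb genes. Sprr2d rose from 7.55 ± 0.427 to 229 ± 31.7 CPM (SD, n = 4), while Sprr1a fell by 0.63 on the log2 scale. The basement membrane collagen genes Col4a1, Col4a2 and Col4a5 fell 3.20-fold, 4.26-fold and 5.95-fold and Col8a1 17.2-fold, whereas Col6a1 and Col7a1 rose 5.24-fold and 2.67-fold. The interleukin-36 gene Il36a and Il33 rose by 5.65 and 2.72 on the log2 scale, and the receptor antagonist gene Il1rn fell 8.45-fold. No member that passed changed sign under the other 3 scalings, and the counts of 2-fold changes stayed the same apart from Cyp rises (4 by library size alone, 5 otherwise). Members of the Sprr and Serpinb families are similar in sequence, and whether their counts share reads was not tested.

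Phosphodiesterase genes other than the Pde4b and Pde4d of the CREB-CRTC list also moved: Pde10a and Pde3b rose by 5.78 and 4.37 on the log2 scale and Pde4a fell by 1.30, while Pde8b had 104 parental and 0 knockout counts, but the family as a whole showed no excess after adjustment (4 of 13 rose at least 2-fold, adjusted p = 0.152). Among the most abundant mRNAs, Gapdh rose from 2671 to 6260 CPM and Ero1a, an endoplasmic reticulum oxidase, from 1070 to 4394 CPM. The mean of the p53 list was -0.181, -0.334, -0.556 and -0.316 in knockout replicates 1 to 4 and within 0.018 of 0 in parental libraries.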
